A study of Aloe vera with 7 samples.

How the data were processed

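The series measured RNA of Aloe vera leaf and root on Affymetrix ATH1 arrays for Arabidopsis thaliana, with 3 arrays per tissue and 1 array of genomic DNA, 7 in all. Total RNA was extracted with a column kit for plants and 250 ng per array was labelled with a 3' IVT kit, per the labels' protocols. The deposited table holds log2 values made with RMA, which corrects background, normalizes arrays by quantiles and summarises probes into probe sets, per the submitters' processing notes; no version is given in the sources used here. The log base is that of RMA's usual output and is not stated. In all 18874 probe sets the median over the 6 RNA arrays was within 1e-06 of 0, as seen from the values, so each probe set had been centred; the centring and any filter behind the listed probe sets are not stated in the sources used here. Direction follows the tissue labels, and the table gives no signal levels; the rounding of the values keeps only a coarse trace of the level before centring, with a coarser grid for higher signal, which entered no test or filter. Array medians of the deposited log2 values were -0.0023, -0.010 and -0.014 for leaf replicates 1 to 3 and 0.017, 0.0019 and 0.0069 for root replicates 1 to 3.

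The column of the genomic DNA array held 0 values. Results planned on it, namely the relation of DNA to RNA signal and the share of calls by DNA signal, were therefore not computed, and without levels neither was any filter on dim probe sets. Whether a probe set lay above background is not known here. No arrays were duplicates: the closest pair, root replicates 1 and 3, had a median absolute difference of 0.301 log2.

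Control probe sets of the array (64) were left out, which left 18810. By the platform's probe annotation, 11100 of these carry 1 gene, 350 several and 7360 none listed; a probe set with several or none is unnamed here. Root minus leaf was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) over the 6 RNA arrays, with no covariate, and called at a Benjamini-Hochberg adjusted p under 0.05. The residual degrees of freedom were 4 and the prior degrees of freedom 3.8. Python 3.11.15, SciPy 1.17.1, pandas 2.3.3 and NumPy 2.4.6 were used for summaries, exact tests and permutation tests with 100000 resamples.

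The test, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The rule names the 12 single-gene probe sets per direction with the largest difference among those called with no overlap between tissues, or all if fewer. In each list it names up to 4 called genes with the largest difference. Where a list had no call, the rule asked for the 2 genes with the highest mean signal, and a further part asked for the brightest probe sets; with no levels given, the 2 genes with the smallest p were taken instead and that further part was not applied. Likewise, genes with several probe sets were represented by the mean of their single-gene probe sets (10991 genes), where the brightest had been planned.

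A gene is called measured here if its name matched a single-gene probe set, which held for 46 of the 414 nuclear genes in the lists. Genes without a match may still lie on the array, among the 7360 probe sets with no gene listed or those with several. By this matching, 7 of the 26 lists had 0 measured genes. The 6 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 6: nuclear photosystem genes, Calvin cycle, chlorophyll biosynthesis, tubulins, chloroplast-encoded genes and mitochondrion-encoded genes. A further 22 lists of gene families were chosen after the data had been seen, from the names present, and adjusted among themselves.

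Leaf and root arrays share replicate numbers, and the labels do not say what a number marks. Deviations from the tissue means correlated between same-numbered arrays by 0.12, 0.37 and 0.25 (Pearson, across probe sets) for numbers 1, 2 and 3, and by -0.29 to 0.064 between arrays of different number. As all 3 exceeded 0.1, the numbers were taken to pair the samples, and the value with the replicate number as a block stands beside a result where it changes a call. This pairing is an assumption. Deviations cancel over the 3 arrays of a tissue, so the correlations depend on each other, and no chance level was computed.

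The test was checked on simulated data with the spread of the real comparison of root against leaf. In 10 simulations over 18810 probe sets, with 200 changed in each, 13.0% of 2-fold, 70.4% of 4-fold and 86.5% of 8-fold changes were recovered, and 4.88% of calls were false. Probe sets were simulated as independent, with normal noise and no replicate pairing, so the rates on the real arrays may differ. The list of 59 chloroplast-encoded genes, shifted by -0.5 log2 with genes simulated as independent, was called in 10 of 10 simulations, and 0 lists were called without a shift. The real genes are correlated, and 7 of the 9 other divisions of the real arrays into 3 and 3 called a list, so these simulations do not give the power or the false calls of the list test on the real arrays.

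Alternatives were probe sets without a shared-sequence suffix, quantile normalization, centring of each array, eBayes with trend and robust fitting, array weights, the replicate block, a 2-fold minimum, camera with an estimated correlation and leaving out each array. One more, without the probe sets of chloroplast-encoded genes, was chosen after seeing the data. The variance trend was fitted on means of the centred values, which carry no signal level.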

Results

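RNA from leaf and root of Aloe vera, a succulent monocot with crassulacean acid metabolism, was hybridised to ATH1 arrays, whose probes were designed for Arabidopsis thaliana. A value therefore reports how much labelled Aloe RNA bound the probes of an Arabidopsis gene, and the gene names are those of the Arabidopsis probe sets. The series holds 7 arrays: 3 of leaf RNA, 3 of root RNA and 1 of genomic DNA. For each RNA array 250 ng of total RNA was labelled. The labels describe 1 mature plant and do not say whether the replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. Each value was a log2 difference from the probe set's median over the 6 RNA arrays, so the table gives differences between tissues and not signal levels. The number of arrays limited the precision, with a median standard error of 0.26 log2 for a root minus leaf difference.

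The comparison of root with leaf RNA asked which Arabidopsis probe sets bound the RNA of the 2 tissues unequally. The largest difference was at AT4G26710, which encodes a membrane subunit of the vacuolar proton pump. It was 216-fold higher in leaf, with a root minus leaf difference of -7.76 ± 0.39 log2 (SE, n = 3 arrays per tissue) and an adjusted p of 0.000601 in limma. Its difference was -7.02 log2 after quantile normalization, a fold over 1.5 times smaller. The photosystem II genes psbZ and psbH, carried in the chloroplast genome, were also higher in leaf. The probe set of psbZ differed by -4.76 ± 0.32 log2 (27.2-fold, adjusted p = 0.00206) and that of psbH by -4.01 ± 0.28 log2 (16.1-fold, adjusted p = 0.00229). In root, AT4G12500, a member of the lipid transfer protein family, was higher by 2.35 ± 0.32 log2 (5.12-fold, adjusted p = 0.0331).

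Of 18810 probe sets tested, 64 passed the adjusted threshold of 0.05 in limma, 52 higher in leaf and 12 higher in root. At an unadjusted p under 0.05 the counts were 918 and 880, and their order turned in several settings: 1133 in leaf and 1184 in root with the replicate number as a block, 920 and 1005 with array weights, 842 and 862 with a variance trend and robust fitting. It also turned without leaf replicate 3 (736 and 743), root replicate 2 (766 and 921) or root replicate 3 (826 and 831). The called differences ranged from 2.62-fold to 216-fold, and 21 of those higher in leaf and 1 of those higher in root exceeded 8-fold. Leaf and root values did not overlap in any of the 64. Over all probe sets 2849 (15.1%) had no overlap, where chance gives 10% for 3 arrays against 3 if all 6 are exchangeable, which leaves any pairing of replicates aside. Of the 64 probe sets, 35 carried 1 gene in the probe table, 30 of them higher in leaf and 5 higher in root; 1 carried several genes and 28 are unnamed here.

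**Figure D1:**
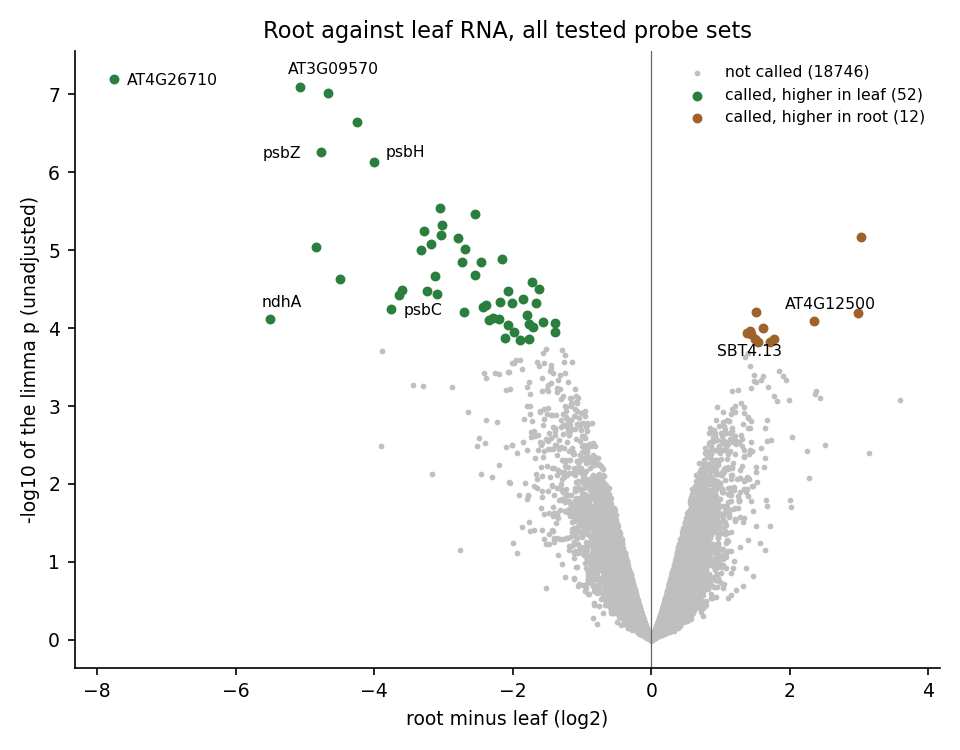
Each point is 1 of 18810 probe sets, with the root minus leaf difference (log2) on the x axis and -log10 of the unadjusted limma p on the y axis. The 52 probe sets called higher in leaf (green) reach -7.76 log2, and the 12 called higher in root (brown) lie between 1.39 and 3.02 log2.

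Among named genes higher in leaf, AT3G09570 differed by -5.07 ± 0.27 log2 (33.6-fold), AT2G14800 by -4.66 ± 0.25 log2 (25.3-fold) and AT4G25330 by -4.24 ± 0.26 log2 (19.0-fold). Their adjusted p-values were 0.000601, 0.000601 and 0.00107. The gene ndhA, for a subunit of the chloroplast NADH dehydrogenase-like complex, differed by -5.51 ± 0.73 log2 (45.4-fold, adjusted p = 0.0327). Its difference was -4.79 log2 after quantile normalization or without root replicate 2, and -6.43 log2 without root replicate 3. Photosystem II genes psbC and psbB, which encode inner antenna proteins, differed by -3.75 ± 0.48 and -3.65 ± 0.44 log2 (adjusted p = 0.0289 and 0.0237), with psbC at -4.36 log2 without leaf replicate 2. AT4G07740 differed by -3.33 ± 0.33 log2, AT1G80950, a phospholipid acyltransferase gene, by -3.27 ± 0.30 log2 and AT4G32630 by -3.09 ± 0.37 log2, with adjusted p-values of 0.0111, 0.0101 and 0.0237. The remaining named genes higher in root were AT3G12510 (1.51 ± 0.19 log2, adjusted p = 0.0301), AT4G24530 (2.83-fold, SE 0.22 log2, adjusted p = 0.0426), the subtilisin-like protease gene SBT4.13 (1.42 ± 0.20 log2, adjusted p = 0.0384) and AT5G22590 (1.39 ± 0.20 log2, adjusted p = 0.0384). AT3G12510, SBT4.13 and AT5G22590 were 2.85-fold, 2.68-fold and 2.62-fold higher. All differences are on 3 arrays per tissue.

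The calls of AT4G26710, AT3G09570, psbZ, AT2G14800, AT4G25330 and psbH held whichever of the 6 arrays was left out. The other 11 of the 17 named probe sets lost the call without at least 1 array, with a highest adjusted p of 0.0574 for AT1G80950 and 0.186 for AT4G24530. Of the 6 fits with an array left out, 0 called AT3G12510, AT4G24530, SBT4.13 or AT5G22590, all higher in root. AT4G12500, ndhA, psbC and AT4G32630 were called in 1 of them, psbB in 2, AT4G07740 in 3 and AT1G80950 in 4. With the replicate number as a block, 5 calls ended: the adjusted p was 0.0508 for psbB, 0.0530 for AT3G12510, 0.0765 for AT4G24530, 0.0651 for SBT4.13 and 0.0742 for AT5G22590. Over all alternatives the adjusted p ranged from 0.00209 to 0.136 for psbB, from 0.00274 to 0.159 for AT3G12510, from 0.00742 to 0.186 for AT4G24530, from 0.00467 to 0.178 for SBT4.13 and from 0.00660 to 0.184 for AT5G22590. With a variance trend and robust fitting, ndhA (adjusted p = 0.308, range over alternatives 0.00546 to 0.308) and psbC (adjusted p = 0.0940, range 0.00270 to 0.150) were not called, and after quantile normalization AT4G24530 was not (adjusted p = 0.0586). That trend and robust fit called 115 probe sets higher in leaf and 40 higher in root. Its trend rested on means of centred values, without signal levels, so this fit does not decide on the calls it gained or lost. Without leaf replicates 1, 2 and 3 in turn, 28, 26 and 7 probe sets were called higher in leaf and 1, 1 and 0 higher in root. Without root replicates 1, 2 and 3 in turn, the counts were 15, 23 and 20 higher in leaf and 1, 2 and 5 higher in root. Of the 64 called probe sets, 7 were called whichever array was left out, 26 were called in none of the 6 fits with an array left out, and 0 changed sign.

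**Figure D2:**
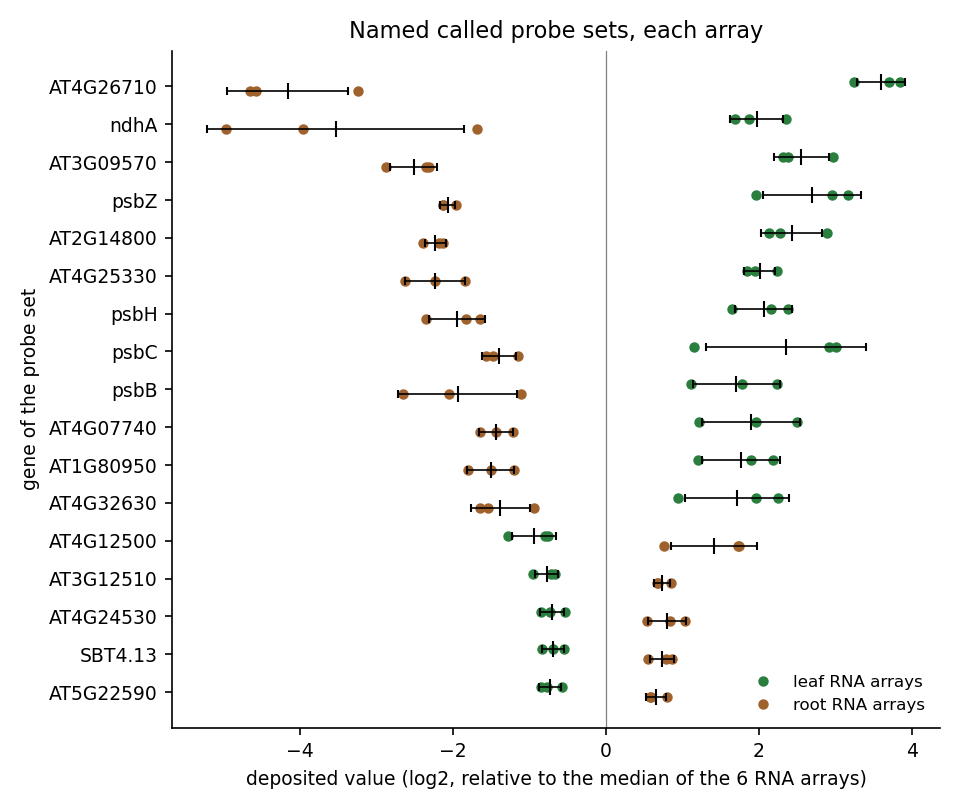
Points are the deposited values of the 3 leaf arrays (green) and 3 root arrays (brown) for the 17 named probe sets, in log2 relative to the median of the 6 RNA arrays; black ticks and bars are the group mean ± SD. Absence of overlap between leaf and root was required for naming; the widest spread is that of ndhA in root (SD 1.68).

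Chloroplast-encoded genes as a group were higher in leaf. Of the 59 measured, 48 had a higher mean in leaf and 11 in root, with a median root minus leaf difference of -0.54 log2 and a mean of -1.04 log2 (limma's camera, adjusted p = 1.78e-16 with the preset correlation of 0.01). With an estimated correlation of 0.222 between the genes the adjusted p = 0.276, and the range over all alternatives was 1.51e-25 to 0.276. Averaged over the 59 genes, the leaf arrays stood at 0.84, 0.097 and 0.81 log2 and the root arrays at -0.59, -0.53 and -0.26 log2. An exact permutation test of these 3 leaf against 3 root means gave a two-sided p of 0.1, the smallest that free reassignment allows. Swapping leaf and root only within the 3 replicate pairs, in all of which leaf was higher, gave an exact two-sided p of 0.25, the smallest that pairing allows. The median was -0.43 log2 without leaf replicate 1 and -0.65 log2 without leaf replicate 2, the extremes over the left-out arrays, and the list was called with the preset correlation in each case.

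Over all genes tested, 7 of the 59 passed the threshold, all higher in leaf: ndhA, psbZ, psbH, psbC, psbB, psbK and atpH. The last 2 fall outside the rule for named genes and were chosen after their values were seen; psbK, of photosystem II, differed by -3.02 ± 0.27 log2 and atpH, of the chloroplast ATP synthase, by -2.45 ± 0.26 log2. Adjusted over the list alone, 19 genes were higher in leaf and 1, atpA of the ATP synthase, was higher in root (1.16 ± 0.26 log2, adjusted p = 0.0110 over the list alone and 0.177 over all genes). The atpA gene, too, was chosen after its value was seen. Grouped by gene name after the values were seen, all 12 photosystem II genes had a higher mean in leaf, with a median of -2.49 log2, and 5 of them passed over all genes. The median was -1.37 log2 over 5 cytochrome b6f genes, -1.30 log2 over 6 ATP synthase genes and -0.35 log2 over 4 photosystem I genes. It was -0.37 log2 over 8 genes of the NADH dehydrogenase-like complex, -0.23 log2 over 13 ribosomal protein genes and -0.36 log2 over 4 RNA polymerase genes. Among the 30 single-gene probe sets called higher in leaf, 7 were chloroplast-encoded against 0.16 expected from the 59 in 11100 single-gene probe sets (Fisher's exact test, two-sided p = 1.54e-10, across probe sets, which are not independent replicates). That background was not matched on signal. Values lay on the coarser rounding grid that higher signal leaves in 83.1% of the chloroplast-encoded probe sets and 62.15% of all 18874 listed. The latter include control and unnamed probe sets, and the share among the 11100 was not computed.

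**Figure D3:**
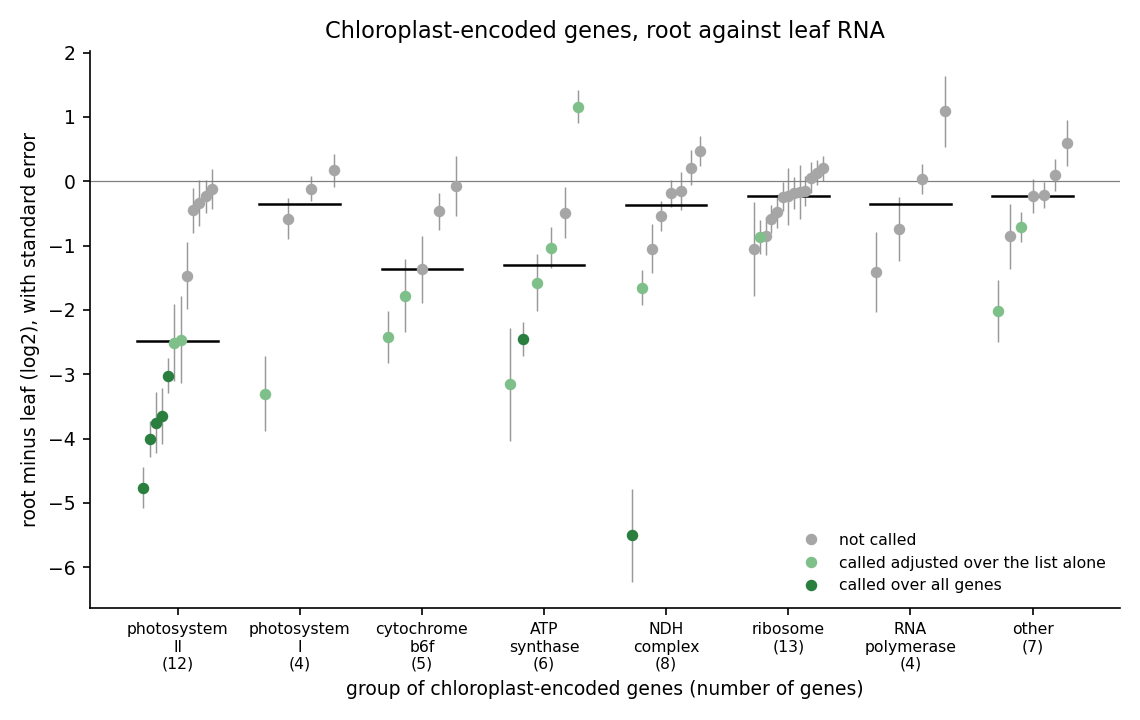
Each point is 1 of 59 chloroplast-encoded genes, grouped by the complex its name gives, with the root minus leaf difference (log2) and its standard error on the y axis; black lines are group medians. The lowest median is that of the 12 photosystem II genes (-2.49 log2), and atpA (1.16 log2) is the only gene above 0 called over the list alone.

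Nuclear genes of photosynthesis did not pass as groups. The photosystem list had been planned as a check of the tissue labels, and that check was not met, with 7 of its 48 genes matched by name. The others may lie on probe sets with no gene listed. Whether these probe sets lay above background is not known, so values near 0 do not show equal RNA in the 2 tissues. The 7 measured genes of photosystems, light harvesting and electron transport had a median of -0.048 log2 and a mean of -0.13 log2 (camera, adjusted p = 0.353). Averaged over the 7 genes, leaf replicates 1 to 3 stood at 0.021, -0.071 and 0.20 log2 and root replicates 1 to 3 at -0.11, -0.21 and 0.088 log2, so leaf was higher in all 3 replicate pairs. Exact permutation tests, two-sided, gave p = 0.25 within pairs, the smallest possible, and p = 0.4 with free reassignment. LHCB4.1 and LHCB4.2, which encode minor antenna proteins of photosystem II, differed by -0.73 ± 0.24 and -0.28 ± 0.22 log2 (adjusted p = 0.374 and 0.790). Over the 5 Calvin cycle and photorespiration genes the median was -0.084 log2 (adjusted p = 0.420). Phosphoribulokinase (PRK) differed by -1.25 ± 0.44 log2 and rubisco activase (RCA) by -0.70 ± 0.29 log2, and the adjusted p over the list alone was 0.106 for both. The 5 chlorophyll biosynthesis genes had a median of 0.30 log2 (adjusted p = 0.353), ranging from 0.12 log2 without leaf replicate 2 to 0.43 log2 without leaf replicate 1, with AT1G74470 at 0.47 ± 0.23 log2 and HEMB1 at 0.39 ± 0.22 log2 (adjusted p = 0.594 and 0.691). In these 3 lists 0 genes passed in limma over all genes, 0 passed adjusted over the list alone, and 3 had an unadjusted p under 0.05. The photosystem median was 0.052 log2 without root replicate 2, and the Calvin cycle median was 0.070, 0.060 and 0.043 log2 without leaf replicate 2, root replicate 1 and root replicate 2.

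The 16 measured mitochondrion-encoded genes had a median of 0.27 log2 and a mean of 0.32 log2, on the root side, and did not pass (camera, adjusted p = 0.0977). With the replicate number as a block the list passed (adjusted p = 0.0420), and with an estimated correlation its adjusted p = 0.494, in a range of 0.0142 to 0.678 over all alternatives. It also passed without leaf replicate 1 (adjusted p = 0.0210), leaf replicate 3 (0.0142) or root replicate 1 (0.0152), while the median was -0.0060 log2 without root replicate 3 (adjusted p = 0.606) and 0.11 log2 without leaf replicate 2 (adjusted p = 0.678). In leaf replicate 2 the control probe set for cytosolic large-subunit ribosomal RNA stood at -4.72 log2, against -0.90 to 1.08 log2 on the other RNA arrays. The control probe set for 5S ribosomal RNA stood at -0.13 log2 in leaf replicate 2. Averaged over the 16 genes, leaf replicate 2 stood at -0.59 log2 and root replicate 3 at 0.59 log2, and the other 4 arrays lay between -0.070 and 0.097 log2. Leaf was higher in 1 of the 3 replicate pairs. Exact permutation tests of these means, two-sided, gave p = 0.5 within pairs (smallest possible 0.25) and p = 0.6 with free reassignment (smallest possible 0.1). Genes of cytochrome c maturation had the smallest p-values, ccb206 at 0.92 ± 0.23 log2 (adjusted p = 0.215) and ccb382 at 0.55 ± 0.24 log2 (adjusted p = 0.530). In this list 0 genes passed in limma over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05.

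The 5 tubulin genes had a median of 0.29 log2 (camera, adjusted p = 0.353), ranging from 0.097 log2 without root replicate 1 to 0.48 log2 without leaf replicate 3. TUB6 was higher in root by 1.68 ± 0.39 log2, which passed adjusted over the list alone (adjusted p = 0.0133) and not over all genes (0.191), and TUB5 differed by -0.84 ± 0.42 log2 (adjusted p = 0.615). In limma 0 of the 5 passed over all genes, 1 passed adjusted over the list alone, and 1 had an unadjusted p under 0.05.

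A further 13 lists had 1 to 4 measured genes, 24 genes in all, and were not tested as groups. In limma 0 of these genes passed over all genes, and 0 passed adjusted over the list alone, while 2 had an unadjusted p under 0.05. In the list of crassulacean acid and four-carbon acid metabolism, the malate dehydrogenase gene AT5G58330 differed by -0.71 ± 0.30 log2 (adjusted p = 0.505) and pyruvate phosphate dikinase (PPDK) by -0.31 ± 0.22 log2 (adjusted p = 0.770). Of glycolysis and fermentation, the lactate dehydrogenase gene AT4G17260 stood at 0.58 ± 0.22 log2 and triosephosphate isomerase (TPI) at 0.40 ± 0.21 log2 (adjusted p = 0.462 and 0.630). Glutathione reductase GR1 stood at 1.19 ± 0.63 log2 and the ascorbate peroxidase gene SAPX at 0.31 ± 0.19 log2 (adjusted p = 0.637 and 0.715). The root hair expansin genes EXPA18 and EXPA7 stood at 0.082 ± 0.24 and 0.084 ± 0.28 log2, the guard cell marker AT1G22690 at 0.11 ± 0.21 log2 and the wax gene WSD1 at 0.21 ± 0.18 log2. For carbohydrate and phenolic pathways the values were 0.071 ± 0.24 log2 for the mannan synthase gene CSLA01, -0.19 ± 0.22 log2 for COB of cellulose deposition, -0.12 ± 0.33 log2 for HCT of lignin synthesis and -0.18 ± 0.41 log2 for DFR of flavonoid synthesis. Of housekeeping and chaperone genes, ACT11 stood at -0.12 ± 0.28, EIF4A-2 at -0.057 ± 0.25, the ribosomal protein genes AT3G09630 and ATL5 at 0.35 ± 0.41 and -0.17 ± 0.30, and the heat shock genes AT3G09440 and Hsp70-2 at 0.18 ± 0.41 and 0.069 ± 0.21 log2.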

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

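The counts of 52 probe sets higher in leaf and 12 higher in root stayed within 1.5 times under probe sets without a shared-sequence suffix, quantile normalization, array centring, array weights, the replicate block (53 and 9, with 47 shared probe sets), a 2-fold minimum and, chosen after seeing the data, the removal of chloroplast-encoded genes (45 and 12). With eBayes trend and robust fitting they were 115 and 40, and 60 of the 64 were shared. That trend was fitted on centred values without signal levels, and the cause of the rise was not tested. With 1 array left out they ranged from 7 to 28 and from 0 to 5, on fewer samples. The replicate block raised the gene lists higher in root from 0 to 1, the mitochondrion-encoded genes (adjusted p = 0.0420 under the block and 0.494 with an estimated correlation, range 0.0142 to 0.678); this count was 0 to 1 with 1 array left out. The block ended 5 calls of named probe sets and changed no other call among the named probe sets and the 6 lists. With an estimated correlation, 0 lists were higher in leaf, since the chloroplast-encoded genes, at -0.54 log2, lost their call (adjusted p = 0.276, range over alternatives 1.51e-25 to 0.276). The photosystem median turned to 0.052 log2 without root replicate 2 (range over left-out arrays -0.15 to 0.052). The Calvin cycle median turned to 0.070, 0.060 and 0.043 log2 without leaf replicate 2, root replicate 1 and root replicate 2 (range -0.35 to 0.070), and the mitochondrial median to -0.0060 log2 without root replicate 3 (range -0.0060 to 0.41); the cause was not tested. Of the 17 named probe sets 0 changed direction, and 10 were called in each alternative named above that kept all 6 arrays and all genes. Filters on dim probe sets or on DNA signal, and the DNA array in the fit, were not run, because no levels were given and the DNA column was empty. How far weak signal limits these results is unknown here.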

Other observations

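The gene families, the test of probe set counts over other divisions of the arrays, the tests on control probe sets (the one for number 3 included) and without chloroplast-encoded genes, and the test on variable probe sets for numbers 2 and 3 were chosen only after results were seen. Among 22 gene families, 0 passed limma's camera, 1 had an unadjusted p under 0.05, and the medians ran from -0.20 to 0.30 log2. The smallest adjusted p was 0.547, for 11 E2 ubiquitin-conjugating enzymes (median -0.19 log2). That family passed without root replicate 1 (median -0.37 log2, adjusted p = 0.0429) and had a median of -0.028 log2 without root replicate 2 (adjusted p = 0.761); with an estimated correlation the adjusted p = 0.907, the highest over its alternatives. In it, UBC29 (-3.44 ± 0.61 log2) and UBC28 (-1.41 ± 0.31 log2) were higher in leaf when adjusted over the list alone, and 0 passed in limma over all genes, with 3 at an unadjusted p under 0.05. The 21 nuclear factors of photosystem and NDH complex assembly had a median of -0.20 log2 (adjusted p = 0.736), which with 1 array left out ran from -0.22 log2 (leaf replicate 2) to -0.058 log2 (leaf replicate 3). LPA1, an assembly factor of photosystem II, stood at -1.58 ± 0.49 log2 (adjusted p = 0.349 over all genes). Adjusted over their own lists, the endoglucanase gene GH9C2 (-1.52 ± 0.23 log2) and the sugar transporter gene SWEET3 (-0.77 ± 0.20 log2) were higher in leaf. The auxin conjugation gene GH3.9 (1.14 ± 0.26 log2), the plant defensin gene PDF1.2 (1.25 ± 0.36 log2) and PR-1-LIKE (0.86 ± 0.25 log2) were higher in root by the same adjustment. These 5 genes did not pass over all genes, and all were chosen after their values were seen.

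In 7 families the median, the mean and camera's direction differed in sign. Expansins and xyloglucan endotransglucosylases had a median of 0.033, a mean of -0.0098 and a test direction toward leaf. For UDP-glycosyltransferases the values were 0.0062 and -0.0084, toward leaf, and for glutathione S-transferases -0.093 and 0.0098, toward leaf. Tetraspanins stood at -0.082 and 0.028 and SWEET transporters at 0.024 and 0.013, both toward leaf. Ubiquitin-specific proteases stood at -0.0082 and 0.066 and defensins with thionins and osmotin at -0.0036 and 0.24, both toward root. None of these passed, with adjusted p-values of 0.812 for the defensin list, 0.947 for glycosyltransferases, glutathione S-transferases and SWEET transporters, and 0.864 for the others.

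Array control probe sets singled out some arrays. Over 24 probe sets of the poly-A spikes the mean was -1.11 log2 in root replicate 1, 0.97 log2 in leaf replicate 3 and 0.73 log2 in root replicate 3, and between -0.21 and -0.011 log2 on the other 3 RNA arrays. The probe set for cytosolic large-subunit ribosomal RNA stood at -4.72 log2 in leaf replicate 2 and between -0.90 and 1.08 log2 on the other 5 RNA arrays. That for 5S ribosomal RNA stood at -0.13 log2 in leaf replicate 2 and between -0.14 and 0.069 log2 on the other 5. The 5 ubiquitin control probe sets stood between 0.49 and 1.34 log2 in leaf replicate 1. Root replicate 2 had 1163 probe sets over 1 log2 from the median, against 404 to 679 on the other arrays. The first 3 principal components held 33.3%, 25.3% and 16.5% of the variance. On the first, leaf replicates 1 to 3 stood at -33.0, 0.9 and -42.5 and root replicates 1 to 3 at 15.0, 58.7 and 0.9. Leaf replicate 2 and root replicate 3 thus coincided on that component only. On the second they stood at opposite ends, at -44.1 and 46.3, with the other arrays between -14.4 and 24.8. With each probe set centred on its mean, leaf replicate 2 correlated with leaf replicates 1 and 3 by -0.12 and -0.070 (Pearson). With root replicates 1 to 3 it correlated by -0.35, -0.014 and -0.46. Other same-tissue correlations were also low, at 0.054 for leaf replicates 1 and 3. Root replicate 1 correlated with root replicates 2 and 3 by -0.017 and 0.049, and root replicates 2 and 3 by -0.19. The same-tissue correlations therefore do not set leaf replicate 2 apart.

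The real division of the 6 arrays into leaf and root called 64 probe sets, and the highest of the other 9 divisions into 3 and 3 called 0, so 1 of 10 gave as many. Among the divisions that also part all 3 replicate pairs, the unadjusted counts were 1798 for the real one and 430, 441 and 539 for the others. Among those that part only 1 pair, the unadjusted counts ran from 647 to 1631. The count of 1631, near that of the real division, came with leaf replicates 1 and 3 and root replicate 3 together. For the 6 gene lists the real division called 1 list with the preset correlation, the highest other called 2, and 8 of 10 called as many as the real one. With 10 divisions no share under 0.05 can be reached.

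Chloroplast-encoded genes were higher on leaf arrays with the preset correlation (7 of 59 called over all genes, 11 with a higher mean in root) and not called with an estimated correlation (adjusted p = 0.276). The median stayed at -0.56 log2 or lower under 2 other scalings, below the bound of -0.5 log2 set in advance. The deposited arrays were already normalized, with medians from -0.014 to 0.017 log2, so these scalings could change little. This argues only against a scaling difference left in the deposited values, and scaling before deposit was not tested. A contribution of a single array stays open: the median passed that bound without leaf replicate 1 (-0.43 log2) and also without leaf replicate 3 (-0.48 log2), although the list kept its preset-correlation call whichever array was left out. Plastid DNA carried over into leaf RNA was expected to shift 36 photosynthesis genes and 18 gene-expression genes alike. Their medians were -1.04 and -0.24 log2 (permutation test across genes, two-sided p = 0.00324). The permutation treats genes as independent replicates, although the estimated correlation between the 59 genes was 0.222, so its p is too small to be taken at face value. That expectation was too simple, because the Arabidopsis probes may match Aloe sequence better for some genes, and with an empty DNA column carry-over cannot be told apart from a difference in RNA between the tissues.

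Same-numbered leaf and root arrays deviated together. A shared labelling or hybridisation run is argued against for the 3 pairs together, since over spiked-in control probe sets the lowest same-number correlation was -0.285 and the highest between different numbers 0.60. For number 3 it stays open, as that pair's spike correlation of 0.693 was the highest of all; the spikes come from few added mixtures, so the test is narrow. Without the tenth of probe sets that varied most, the correlation of number 1 went from 0.117 to 0.091. It crossed the bound of 0.1 set in advance, as predicted if a few variable probe sets were the cause. It kept most of its size, a criterion added after the value was seen, so this does not decide for that pair. Numbers 2 and 3 stayed above the bound, at 0.25 and 0.173, which argues against a few variable probe sets there, and whether a number marks a plant or a day was not tested.

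More probe sets were called higher in leaf than in root. At least 81.8% of calls were higher in leaf under 2 other scalings, above the bound of 60% set in advance. As the deposited arrays were already normalized, this argues only against a scaling difference left in the deposited values. The chloroplast-encoded genes as the whole cause are argued against (78.9% without them). Leaving out 1 array does not decide: at least 80.0% of calls were then higher in leaf, but few calls remained, and at an unadjusted p under 0.05 root led without leaf replicate 3, root replicate 2 or root replicate 3. A hypothesis that stays open is a difference between the tissues in RNA that binds these probes, which was found and examined on the same 6 arrays.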
